A study of Arabidopsis thaliana with 2 samples.

How the data were processed

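Total RNA of plants labelled as flower buds, grown at 20 °C with 16 h of light and 8 h of dark, was sequenced by the authors as 50-nt single-end reads from TruSeq libraries that do not keep strand, per the labels' protocols. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart. Each of the 2 samples, wild type and ago1-27, was described as holding 3 replicates. TopHat2 2.0.11 and the genome build TAIR10 are named in the submitters' processing notes. The counting tool, the treatment of multiply mapped reads, the test behind the table and its limits are not given in the sources used here.

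The deposited table gave 1 RPKM value (reads per kilobase of transcript, scaled to the library's mapped reads) per genotype and the ratio of ago1-27 to wild type, per the file headers. The deposited ratio matched the quotient of the RPKM columns to a relative difference of at most 4.17e-08, so ratios here are that quotient. The RPKM columns carry no replicate values, so no limma, camera or other test was run, and the branch of the design set for a table without replicates was used. All choices of tests, lists and named genes were fixed before the data were examined, except where said otherwise.

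A gene counted as higher or lower at an absolute difference of at least 1 in log2(RPKM + 1), with RPKM of at least 1 in either genotype, which left out 185 of 6791 genes. The pseudocount of 1 understates the change of low genes, so the text prints ratios of the RPKM values and uses the log2 scale for the threshold and the lists. In each of 17 gene lists written from general knowledge, members were kept where the list's symbol matched the reference symbol or a synonym, apart from a prefix or suffix, or where the reference gave no symbol or the list gave a protein class. This left out 2 members and kept 384 entries. Of the gene identifiers in the table, 6772 were found in the TAIR10.1 annotation and 19 were not. Coordinates and transcript lengths come from TAIR10.1, not from the authors' TAIR10 annotation.

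For every list with at least 5 members compared, the median log2 ratio was ranked among 10000 random lists of the same size, drawn from the table's own genes in the same of 10 bins of mean expression. The percentile describes these values, 1 per genotype, and is not a p-value. Tested on simulated data with ratios shuffled over 6606 genes, 1 of 12 lists fell outside the central 95%, and the target list reached percentile 100 after 1 was added to its log2 ratios.

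Library sizes were read from the steps of low values, since 1 read in a gene of known length has a fixed RPKM at a given library size. Totals between 8000000 and 20000000 were searched. The 3 totals found for wild type each made 38 to 47 genes whole at annotated lengths and the next best total 19. The 3 for ago1-27 made 32 to 42 genes whole and the next best 18. Tested on simulated data for 6772 genes, the totals were recovered, 599 of 600 rows made from 1 library were found and 0 rows made as a mean of 3 were mistaken for them. In the real table, 678 rows (9.98%) had both values equal to whole reads of 1 library per genotype, and most other rows could not be split into replicates with certainty, so no replicate values are used. Reads behind a value were estimated from its RPKM, the TAIR10.1 transcript length and the mean library size of 11845532 reads for wild type and 11955563 reads for ago1-27. The median gene had about 133 wild-type reads in 1 library. Exact (Clopper-Pearson) intervals at 95% on the ratio of those reads are approximate, because lengths differ between annotations. They are wide where a value is a mean of several libraries, and they leave out all variation between plants.

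Genes were named by a fixed rule. AGO1 was always named. From each list came up to 4 members past the threshold with the largest absolute log2 ratio, up to 10 from the conserved miRNA targets, or the member with the largest where none passed. The 8 largest rises and 8 largest falls among genes with RPKM of at least 5 in either genotype were added. Other genes that the text names, such as AP1, LFY, SEP4, STP9, RCA, CCS, APS3 and the remaining miRNA targets, were chosen after their values were seen. Alternatives were pseudocounts of 0.1 and 0.5, no filter, RPKM of at least 5, rescaling by the median of ratios and quantile normalization. After the data were seen, the ratio without a pseudocount and the table without rows from 1 library per genotype were added. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.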

Results

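The series profiled transcripts of Arabidopsis thaliana by RNA sequencing in wild-type plants and in ago1-27, a weak allele of ARGONAUTE1 (AGO1), the protein that carries most plant microRNAs (miRNAs) to their target transcripts. The tissue was labelled as flower buds. Each genotype was described as 3 biological replicates. The values came as 1 RPKM value per genotype for 6791 genes, so no difference below has a replicate check, an SD or a p-value. In 678 of the rows both values equalled whole reads of 1 library per genotype. The low RPKM values moved in steps from which the library sizes could be read, at 13887069, 10453032 and 11196495 reads for wild type and 11407616, 12164864 and 12294210 reads for ago1-27. Intervals are 95% exact binomial intervals on the ratio of reads, taken at the depth of 1 average library, and cover counting error only.

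The table was a selection of genes that differed. It held 4711 genes with a higher value in ago1-27 and 2080 with a lower one. The lowest ratio above 1 was 1.5001, and 1 gene alone lay between the limits of 1.5-fold in either direction, so a gene outside the table may have been unchanged or may have missed a rule that the sources used here do not state. At an absolute log2 ratio of at least 1, on the log2(RPKM + 1) scale and with RPKM of at least 1 in either genotype, 748 genes were higher and 694 lower in ago1-27, of 6606 genes compared. The median log2 ratio of all rows was 0.70. Setting that median to 0 by the median of ratios gave 219 higher and 1970 lower genes. Quantile normalization gave 393 and 1214, so the split between the directions rests on the deposited scale. The median of ratios presumes that most genes do not differ, which a table selected for differing genes does not meet. Under it, ratios just above 1.5 fall below 1 by construction, which alone does not show that their direction is wrong.

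AGO1 itself was 3.29-fold higher in ago1-27 (95% interval 3.14 to 3.45), at 175 RPKM against 53.1 in wild type. AGO1 (AT1G48410) lies on chromosome 1 from 17885633 to 17892632 in TAIR10.1, and its transcript is the target of miR168. The allele leaves the transcript in place, so this value does not check the genotype labels in the way a deletion would.

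The first question, from the series title, was which miRNA targets differ when AGO1 function is reduced. Transcripts of the conserved miRNA targets in the table were mostly higher in ago1-27. Of 89 targets in the list, 49 were in the table, 43 of them higher and 6 lower, and 35 of the 49 remained above 1 after rescaling by the median of ratios. Among the 48 with RPKM of at least 1, 24 passed the threshold upwards and 4 downwards. These counts were 11 and 6 after rescaling by the median of ratios and 16 and 4 after quantile normalization. Their median log2 ratio was 0.99, above the 95% range of random lists matched on expression, which ran from 0.56 to 0.69. No random list of 10000 reached it, a percentile of 100.

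The miR169 and miR156 families stood out. All 6 targets of miR169 in the table, subunits A of the nuclear factor Y transcription factor, were higher, by 2.05-fold to 14.1-fold. NF-YA2 (AT3G05690, chromosome 3, 1676504 to 1679061) was at 3.68 RPKM in wild type and 52.0 in ago1-27, a ratio of 14.1 (11.3 to 18.0). NF-YA3 was 5.23-fold higher (4.02 to 6.86) and NF-YA5 4.70-fold higher (3.23 to 6.93). All 9 targets of miR156 and miR157 in the table, SQUAMOSA promoter-binding protein-like factors of the juvenile-to-adult transition, were higher too. SPL3 (AT2G33810, chromosome 2, 14305001 to 14306072) was 6.13-fold higher (4.65 to 8.19) and SPL5 4.37-fold higher (3.37 to 5.79). These 15 genes kept their direction after both rescalings.

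All 3 targets of miR398 in the list were higher. CSD2 (AT2G28190, chromosome 2, 12014412 to 12016569), the plastid copper/zinc superoxide dismutase, was at 95.6 RPKM in wild type and 399 in ago1-27, a ratio of 4.18 (3.92 to 4.45). CSD1, the cytosolic enzyme, was 3.94-fold higher (3.501 to 4.43). CCS, the copper chaperone of both, was 2.90-fold higher. All 7 targets of miR396 in the table were higher, led among the named genes by the growth regulator GRF3 at 3.81-fold (3.33 to 4.35). Both laccases of the miR408 list in the table, LAC3 and LAC13, were 2.85-fold and 2.57-fold higher. These miR398, miR396 and miR408 targets also stayed above 1 after both rescalings.

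**Figure D1:**
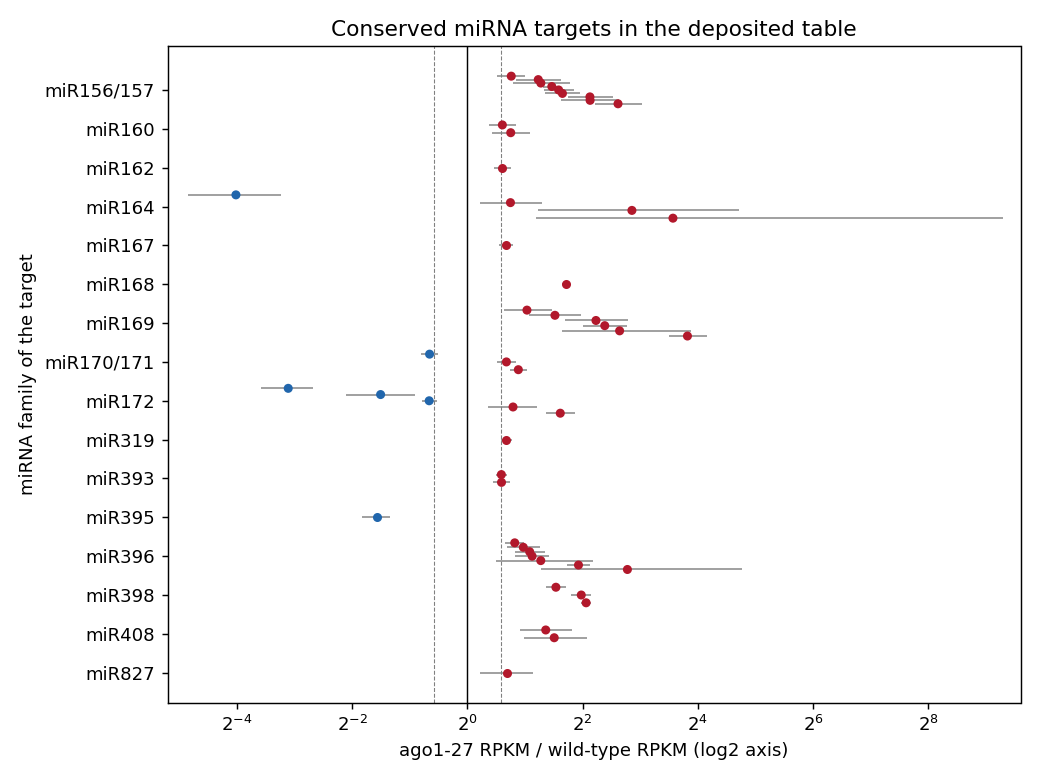
Ratio of ago1-27 to wild-type RPKM (log2 axis) for the 49 conserved miRNA targets in the table, grouped by miRNA family. Each point is a gene, red above and blue below a ratio of 1, each bar is the 95% counting interval, and dashed lines mark 1.5-fold. Of the points, 43 lie above 1 (35 after rescaling by the median of ratios), and the 6 below include NAC092 and SNZ.

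Other conserved targets were lower. NAC092 (AT5G39610, chromosome 5, 15858398 to 15859911), a NAC factor of leaf senescence and a miR164 target, was 16.2-fold lower in ago1-27 (9.39 to 28.7), at 15.1 RPKM in wild type and 0.935 in ago1-27. The other 3 miR164 targets in the table, NAC1, CUC1 and CUC2, were higher, but at low levels. CUC1 was at 0.083 RPKM in wild type, about 1 read, and 0.983 in ago1-27, and CUC2 at 0.217 and 1.57. NAC1 was at 1.77 and 2.98, values from 1 library per genotype. The miR172 targets went both ways. The flowering repressor SNZ was 8.62-fold lower (6.37 to 11.9), and SMZ and TOE1 were lower as well, while AP2 was 3.06-fold higher (2.57 to 3.67) and TOE3 was higher. APS3, an ATP sulfurylase and the single miR395 target in the table, was at 23.9 RPKM in wild type and 8.01 in ago1-27. Of the miR171 targets, the GRAS factors HAM1 and HAM2 were higher and HAM3 was lower, and HAM2 fell below 1 after rescaling by the median of ratios. None of the 8 miR159 targets and none of the 5 targets of miR165 and miR166 in the list was in the table. The targets of miR160, miR162, miR167, miR319, miR393 and miR827 in the table were 1.51-fold to 1.69-fold higher, and 1 of these 8, ARF17, was still above 1 after rescaling by the median of ratios.

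Less conserved targets in the table were also mostly higher. Of 36 in the list, 19 were in the table, 18 of them higher. Among the 18 with RPKM of at least 1, 17 were higher (94.4%), above the 95% range of matched random lists, which ended at 88.9%. For the conserved targets this share was 87.5% against an upper limit of 83.3%. The comparison of shares was not part of the design, which set the percentile of the median and the count past the threshold. It is given here for these 2 lists only. After rescaling by the median of ratios, 15 of the 19 remained above 1. Of the less conserved targets 2 passed the threshold upwards with the pseudocount of 1, 7 with 0.5, 8 with 0.1 and 9 without one. After rescaling by the median of ratios 1 passed upwards and 1 downwards, and 1 passed upwards after quantile normalization or with RPKM of at least 5. Their median log2 ratio of 0.67 was at percentile 68.9 of the random lists, inside their range. The difference between the 2 lists was not tested. FAMT, a methyltransferase targeted by miR163, was 6.44-fold higher (3.61 to 12.1), and the miR824 target AGL16 was 2.25-fold higher (2.04 to 2.49), below the threshold after both rescalings. All 10 targets of miR161 and miR400 in the table, pentatricopeptide repeat genes with close paralogs, were higher, 9 of them after rescaling by the median of ratios. Reads of 50 nt may be split among such copies. They make up 10 of the 19 less conserved targets in the table, and the random lists, matched on expression only, do not allow for linked members. The share of 94.4% is therefore not one of 18 separate observations.

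Transcripts that feed or answer to trans-acting siRNAs had ratios on both sides of 1. The precursors TAS1B, TAS1C and TAS2 were 1.97-fold, 1.98-fold and 1.90-fold higher. Of the ta-siRNA targets in the table, ARF3 and the anthocyanin regulators PAP1 and PAP2 were lower and HTT2 was higher, HTT2 falling below 1 after rescaling by the median of ratios. PAP2 was 9.98-fold lower (2.45 to 89.1) and PAP1 4.95-fold lower (1.90 to 16.9), both from under 2 RPKM in wild type. The list's median was at percentile 27.4, and at 87.7 among genes with RPKM of at least 5, which leaves out PAP1 and PAP2. In the list of small RNA machinery, all 7 genes in the table were higher, 4 of them after rescaling by the median of ratios. Besides AGO1, RDR1, an RNA-dependent RNA polymerase, passed the threshold at 2.95-fold (2.51 to 3.48), but not after rescaling by the median of ratios, at a log2 ratio of 0.76. The median of this list was at percentile 35.0.

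Heat shock transcripts were lower in ago1-27. All 9 of the 13 listed genes that were in the table were lower and passed the threshold, and none of 10000 random lists had as low a median, which was -1.9997 on the log2 scale. HSFA2 (AT2G26150, chromosome 2, 11135624 to 11137792), a heat-inducible transcription factor, was at 20.9 RPKM in wild type and 0.704 in ago1-27, 29.7-fold lower (17.9 to 51.7). The chaperone HSP70-4 was 15.1-fold lower (12.3 to 18.6). HSP90.1 was 9.48-fold lower (7.67 to 11.8). The small heat shock protein HSP17.8-CI was 8.34-fold lower (5.35 to 14.3).

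Photosynthesis, auxin and flavonoid genes in the table were also mostly lower. All 8 photosynthesis genes in the table, of 21 in the list, were lower, with a median at percentile 0.79. LHCB2.1 was 3.26-fold lower (2.82 to 3.76), LHCB2.2 3.09-fold (2.44 to 3.95), LHCB1.1 2.94-fold (2.62 to 3.302) and LHCB3 2.19-fold (2.03 to 2.36). The first 3 encode light-harvesting proteins with near-identical copies, so their reads may be shared. Of 8 early auxin response genes in the table, 7 were lower, at percentile 0.40. IAA1 was 2.99-fold lower (2.18 to 4.22) and IAA3 2.49-fold lower (2.11 to 2.94), both repressors of auxin signalling. Of 9 flavonoid and anthocyanin genes in the table, 8 were lower, including PAP1 and PAP2. The percentile of this list was 1.64 and left the outer 2.5% with the other pseudocounts or none, both rescalings and the higher RPKM limit.

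Jasmonate and salicylic acid genes moved in both directions. Of 9 jasmonate genes in the table, 5 were lower and 4 higher. VSP1, a vegetative storage protein, was 13.0-fold higher (10.14 to 16.8), whereas the signalling repressor JAZ7 was 8.01-fold lower (3.101 to 25.6), the lipoxygenase LOX4 3.496-fold lower (2.88 to 4.29) and AOS, an enzyme of jasmonate synthesis, 2.26-fold lower (2.097 to 2.44). The list's median was at percentile 0.475, and at 9.98 among genes with RPKM of at least 5. Of 12 salicylic acid and defence genes in the table, 8 were higher, 7 of them after rescaling by the median of ratios. The pathogenesis-related genes PR2, PR1 and PR5 were 5.02-fold (3.99 to 6.34), 4.32-fold (3.27 to 5.70) and 3.63-fold (2.86 to 4.63) higher. The transcription factor WRKY70 was 3.93-fold lower (3.53 to 4.40). The median was at percentile 97.9 and fell inside the central 95% under 6 of 8 alternatives.

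**Figure D2:**
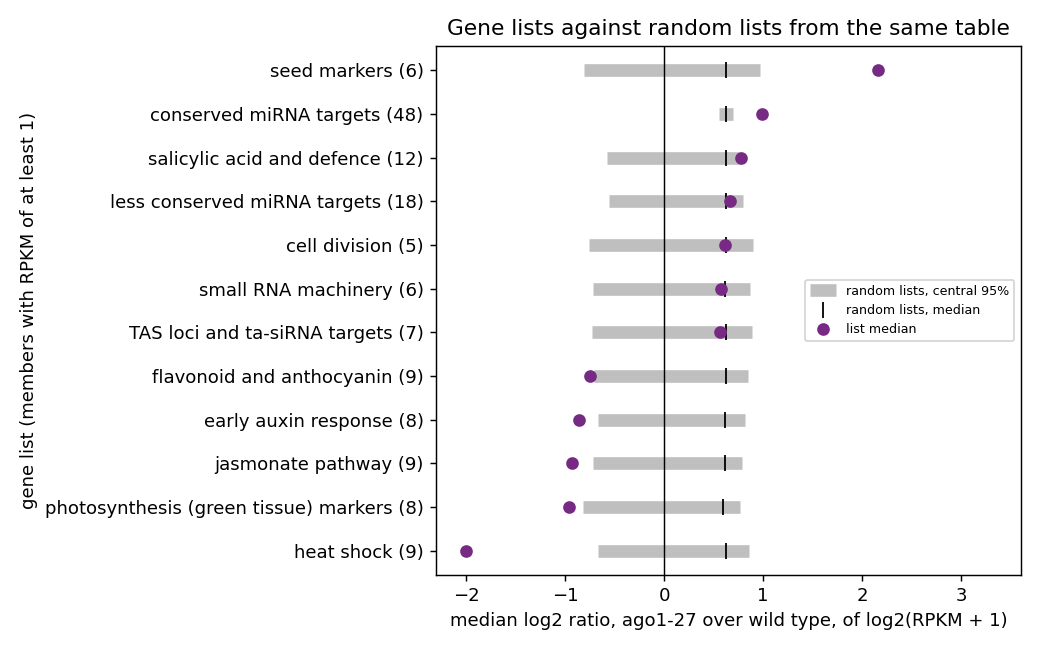
Median log2 ratio, ago1-27 over wild type, of each gene list with at least 5 members with RPKM of at least 1 (purple points), with the number of members after the name. Grey bars give the central 95% and ticks the median of 10000 random lists drawn from the same table and matched on expression. Heat shock genes lie lowest at -1.9997 and seed markers highest at 2.16. After rescaling by the median of ratios the medians of cell division, small RNA machinery and TAS genes lie below 0.

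Seed storage transcripts were higher from very low levels. All 6 seed markers in the table, of 12 in the list, were higher, and none of 10000 random lists had as high a median, which was 2.16. SESA3, a seed storage albumin, was at 0.116 RPKM in wild type and 10.6 in ago1-27, a ratio of 91.0 whose interval ran from 16.8 to 3835 because the wild-type value amounts to about 1 read. SESA2 was 16.5-fold higher (5.56 to 86.0), CRU3, a cruciferin, 14.0-fold (9.14 to 21.9) and CRA1 6.06-fold (4.07 to 9.29). The albumin genes are close copies of each other.

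Few markers of flower parts were in the table. Of 21 genes of floral meristem and organ identity, 5 were in the table, 4 of them higher. FUL was 3.101-fold higher (2.24 to 4.39), at 3.22 RPKM in wild type and 9.98 in ago1-27, and AP2 was at 7.72 and 23.63 RPKM, both below the threshold after rescaling by the median of ratios. SEP4 was at 12.5 RPKM in wild type and 6.22 in ago1-27. The medians of the whole table were 7.11 RPKM in wild type and 9.29 in ago1-27. AP1, which specifies sepals and petals, was at 0.0779 RPKM in wild type and 0.733 in ago1-27. LFY was at 0.151 and 1.17, each equal to whole reads of 1 library of its genotype. By contrast, RCA, the activase of Rubisco, had the highest wild-type value of the table, at 5341 RPKM against 3390 in ago1-27. Of 18 pollen markers 3 were in the table, AGP6 and ANX1 higher and STP9 lower. AGP6 was at 0.377 RPKM in wild type and 1.49 in ago1-27, past the threshold with the smaller pseudocounts or none, and STP9 at 0.917 and 0.167, 5.49-fold lower (1.79 to 21.2). The exine gene LAP6 was the single tapetum marker, 2.32-fold higher (1.73 to 3.098), below the threshold after both rescalings. The single gynoecium and ovule marker, SPT, had values of 2.24 RPKM in wild type and 4.003 in ago1-27, each equal to whole reads of 1 library of its genotype. Of 18 cell division genes 5 were in the table and none passed the threshold. CYCD3;1 had the largest ratio, 1.75 (1.54 to 1.98), and the median was at percentile 44.8, with 2 of the 5 above 1 after rescaling by the median of ratios. Of 8 reference genes, 1 was in the table, GAPC2, at 770 RPKM in wild type and 505 in ago1-27, past the threshold after rescaling by the median of ratios alone.

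The largest differences lay outside the lists in several cases. Among genes with RPKM of at least 5 in either genotype, the 8 largest falls on the log2(RPKM + 1) scale included 3 genes of sulfur assimilation or sulfur deficiency. APR1 (AT4G04610), an APS reductase, was at 187 RPKM in wild type and 9.48 in ago1-27, 19.7-fold lower (17.2 to 22.7). LSU1 was 29.1-fold lower (15.8 to 67.2) and LSU3 25.5-fold lower (14.9 to 49.1). SPX1, a sensor of phosphate status, was 23.1-fold lower (16.7 to 32.6). AT4G22485, annotated as a lipid-transfer protein, was 37.9-fold lower (32.3 to 45.1), and AT2G20670 was 16.6-fold lower (14.4 to 19.3). The F-box gene AT1G73120 was at 29.0 RPKM in wild type and 0.145 in ago1-27, about 1 read. HSFA2 completed the 8.

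Among the 8 largest rises were NF-YA2, VSP1 and SESA3. MC2 (AT4G25110), a metacaspase, was 27.1-fold higher (17.9 to 43.9), at 1.02 RPKM in wild type and 27.7 in ago1-27. PCR1, a cadmium resistance protein, was 17.56-fold higher (11.5 to 29.1). AT3G61280, annotated as a glucosyltransferase, was 15.5-fold higher (12.0 to 20.7). The defensin PDF1.2 was 11.5-fold higher (8.10 to 16.5). The uncharacterized AT4G19430 was at 0.245 RPKM in wild type and 11.1 in ago1-27, and the wild-type value amounts to about 2 reads.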

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

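The last 2 of the 8 alternatives, without a pseudocount and without rows from 1 library per genotype, were chosen after the data were seen. The count of genes past the threshold, 1442, became 2336 with a pseudocount of 0.1, 2442 without one and 2189 after rescaling by the median of ratios. Higher genes, 748, became 1350, 1425 and 219 under these, and 393 after quantile normalization. Lower genes, 694, became 1970 after the median of ratios and 1214 after quantile normalization. A smaller pseudocount lets low genes pass by construction, and both rescalings move a table whose median log2 ratio is 0.70 towards 0. Conserved miRNA targets past the threshold, 28 with 24 higher, became 17 with 11 higher after the median of ratios. Lists with a median outside the central 95% of random lists, 8 of 12, became 4 of 11 with RPKM of at least 5. Part of that drop is by construction, since the seed markers kept 4 members there and were not ranked. The jasmonate, salicylic acid and flavonoid lists moved inside the range too. The limit changes only which genes are compared, and these lists went from 9 to 8, 12 to 10 and 9 to 6 members. The jasmonate median went from -0.9313 to -0.1699, with 4 members higher and 4 lower left. The salicylic acid median stayed at 0.7779. Of the 57 genes named by the fixed rule, 38 moved beyond their counting interval after the median of ratios, 10 after quantile normalization, 8 without a pseudocount and 6 with 0.1. None changed sign, which the pseudocounts and filters cannot cause, nor the median of ratios for a lower gene. No paired analysis was possible because each genotype has 1 pooled column. For the same reason the planned limma fits without trend, with robust estimation, with a replicate block or with each replicate left out, the adjusted p limits, camera with an estimated correlation and fry were not run. Depth limits the low genes most: the gene at percentile 10 had about 19 wild-type reads in 1 library.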

Other observations

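All tests in this part, and its gene lists other than the heat shock and floral lists, were chosen after the values were seen, so counts of members are descriptions and not independent evidence, and a high count on such a list leaves an explanation open. Sulfur deficiency genes were mostly lower in ago1-27: of 19 genes, 13 were in the table, 10 lower and 3 higher, and 7 were at least 4-fold lower. APR3 was at 259 RPKM in wild type and 32.6 in ago1-27, APR2 at 289 and 66.8, LSU2 at 85.4 and 6.72, and SHM7 at 228 and 26.7. The 3 higher genes were the vacuolar sulfate transporters SULTR4;1 and SULTR4;2 and BGLU28. All 10 phosphate deficiency genes in the table, of 20, were lower, among them GDPD1 at 65.8 and 4.45 RPKM, PAP17 at 21.8 and 3.79, and PS2 at 5.32 and 0.432. Genes that respond to sugar or darkness went both ways, with 6 lower and 4 higher of the 10 in the table, 2 of them higher after rescaling by the median of ratios.

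Noncoding genes in the table were mostly higher. Of 89 genes annotated as long noncoding RNA in TAIR10.1, 73 were higher, as were 45 of 53 pseudogenes, against 4496 of 6525 protein-coding genes. Of 9 miRNA genes, 6 were lower, among them MIR156c at 2.27 RPKM in wild type and 0.316 in ago1-27, and 3 were higher, among them MIR157c at 3.23 and 11.9. These loci are short, and the libraries kept no strand. The excess of higher genes shrank with the size of the difference. It was 3178 against 986 between 1.5-fold and 2-fold, 1151 against 713 between 2-fold and 4-fold, and 382 against 380 at 4-fold or more. The 678 rows with values from 1 library per genotype fell in 3 of the 9 possible pairings of the libraries, with 207, 226 and 245 rows, and none in the other 6. Each library was in 1 of these pairings only, so the libraries were matched in pairs in these rows. Whether the other rows average all pairs or only some is not known.

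The lower heat shock transcripts came with lower transcripts of many genes that respond to touch, wounding or cold. Of 18 such genes in the table, 16 (88.9%) were lower in ago1-27, such as TCH4 at 685 and 130 RPKM, WRKY33 at 125 and 30.0, and CBF1 at 1.22 and 0.0463, and 2 cold-regulated genes, COR15B and KIN1, were higher. Of the 9 heat shock genes, 0 had values taken from 1 library per genotype alone, but a mean can be carried by 1 high wild-type library, and that stays open because the replicates could not be split. Handling or stress of the wild-type plants before freezing may have raised both groups there, but it cannot be told apart from an effect of the genotype, which predicts the same. Harvest at another time of day cannot be told apart from it either. The 7 morning genes of the clock in the table were lower, including CCA1 at 3.13 and 0.593 RPKM. Of the 3 genes of the evening list in the table, GI, at 0.858 and 0.236 RPKM, and PRR5 were lower too. The other gene, CO, which is not itself part of the clock, was higher.

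The rise of the miR398 targets CSD1, CSD2 and CCS remained after both rescalings, and the lowest of their log2 ratios was still 0.84 after the median of ratios. That covers a shift of 0.70 only. The true scale error is not known, because the median of ratios presumes that most genes do not differ. A candidate explanation is a smaller supply of miR398 rather than, or besides, a weaker AGO1. The precursor loci MIR398b and MIR398c were at 51.7 and 49.0 RPKM in wild type and at 20.3 and 23.8 in ago1-27. They were 2.55-fold (1.63 to 4.12) and 2.06-fold (1.33 to 3.21) lower, from about 71 and 67 wild-type reads in 1 library. These loci are short, and without strand any antisense reads there would be counted with the precursor. All 6 copper deficiency genes in the table, 100%, were lower, but MIR398b and MIR398c are themselves among the 6, so the count partly restates their fall. The rest were FSD1 at 293 and 152 RPKM, COPT2 at 15.7 and 8.88, CCH at 218 and 143, and YSL2 at 24.6 and 8.99. Lower is the direction that more available copper in ago1-27 would give. The other 4 of the 10 genes were not in the table, the list was put together after MIR398b and MIR398c had been seen to be lower, and both this explanation and reduced AGO1 activity stay open.

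The values of some flower and leaf genes raise a question about the tissue label. AP1 and LFY stayed at or below 1.17 RPKM in both genotypes, with 6753 and 6692 of the 6791 rows above them in wild type, while RCA was at 5341 RPKM. The wild-type values amount to about 1 read for AP1 and 2 reads for LFY in 1 library. Both LFY values equal whole reads of 1 library per genotype, so they do not speak for all replicates. As a hypothesis, the libraries may hold mostly green tissue and little floral tissue. The floral genes in the table cannot settle it. Of the 5, AP1, LFY and FUL lay below the wild-type median of 7.11 RPKM, and 2 lay above it, SEP4 at 12.5 and AP2 at 7.72. That median is of a table selected for differing genes, so a place above or below it does not show how much floral tissue was present. The levels of the other 16 floral genes were not analysed here, so the hypothesis stays open. For these levels the design names no second tissue to compare with, so no biological explanation of them was tested.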
